A study of Mus musculus with 16 samples.

How the data were processed

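RNA abundance was measured on 16 single-colour Agilent mouse arrays, 4 for each of 4 sorted cell populations from untreated C57BL/6 mice. Per the labels, heart tissue was minced and digested, live cells that excluded the dye DAPI were sorted, and all 3 macrophage gates required CD45, MerTK and CD64 and excluded Ly6c. CD45 marks cells of blood origin, and MerTK and CD64 are surface receptors of tissue macrophages. CCR2+ macrophages were CCR2-high and MHCII-high. MHCII-high macrophages were CCR2-negative, MHCII-high and CD11c-low, and MHCII-low macrophages were CCR2-negative, CD11c-negative and MHCII-low. Blood Ly6c-high monocytes were the fourth population. Cells were sorted into Trizol, RNA was purified on columns, and 1 ng of RNA per sample was labelled with Cy5. The labels do not say whether replicates came from separate mice, or whether the same mice gave several populations.

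The scanner files were made by the authors with Agilent Feature Extraction 11.5.1.1, and per the file headers their processed signal is an intensity in arbitrary units, background-subtracted and detrended within each array, with substitute values for dim spots and no scaling between arrays. The deposited value table holds log2 signal, with 1 shared distribution over its 16 columns. Partek is named for the authors' processing without a version or a step. Each column of this table matched the scanner array of a sample other than the one it is labelled with, and 12 of the 16 matched an array of another group. Correlations across probes were at least 0.995 with the matching array and at most 0.969 with the array under the same label. All results below therefore used the scanner files with their own labels, and the value table served only as an alternative. Array position on the slide was the same for all arrays of a group, so position and group cannot be told apart. Replicate numbers coincided with the 4 slides, each of which held 1 array per group.

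Each array had 44397 spots, of which 1377 were controls. In 15 of the 16 files the headings of the text columns were shifted against their contents and in the other they differed, so the columns were found from their contents. Spots marked as non-uniform or as population outliers were left out, and 110 of 39429 probes with no unmarked spot on some array were dropped. Spots of the same probe were averaged. Between 52.8% and 69.3% of spots per array were well above background, the 75th percentile of the processed signal lay between 819 and 1670, and no spot was saturated. Within a group, correlations between arrays across probes ran from 0.916 to 0.981, and the median SD per gene was 0.391 to 0.433 on the log2 scale. The number of arrays limits the precision.

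Signals were put on the log2 scale and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on at least 4 of the 16 arrays, which left 27643 probes. For genes with several kept probes the brightest on average was used, which gave 21897 genes or unnamed features to test, 17257 of them with a symbol. Symbols came from RefSeq accessions for 27508 probes. Probes were not placed on a genome here. The grid headers name the mouse build mm9, which plays no part in the values.

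Groups were compared with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 16 arrays with lmFit and eBayes, without a block, leaving 12 residual degrees of freedom. The 7 comparisons were all 6 pairs of groups and the mean of the 3 macrophage groups against monocytes. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were counted. Counts at an unadjusted p under 0.05 are printed beside some low counts. Chance alone would give a share of about 0.05 of the genes tested there. Where no probe of a gene was well above background on any array of a group, the difference is given as "at least N-fold", with that group set to the lowest signal called well above background on each of its arrays or to its own signal where that was higher, and no log2 value is printed. The adjusted p printed beside such a fold is that of the limma difference without the bound, and the bound itself was not tested. Medians of lists are given a second time with such genes at this bound, and at 0 where both groups were dim, where that moved a printed median by more than 0.1.

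There were 28 gene lists, drawn up before the data were examined from general knowledge of macrophages, monocytes and other heart and blood cells. Some of that knowledge comes from published work on heart macrophages, possibly on these samples, so the lists for resident macrophages and Ly6c-high monocytes are not independent evidence of their direction. Several lists also share members and are not separate evidence. The resident macrophage list shares Mrc1, Cd163, Ccl24, Folr2 and Stab1 with alternative activation. It shares Timd4, Gas6, Stab1 and Cd163 with efferocytosis, and Vsig4 with complement. The list for gate markers checks the sort. Some gate genes are on other lists too, so part of those results was set by the sort. Ccr2 and Ly6c1 are on the Ly6c-high monocyte list and the H2 genes on the class II list. Mertk is on the core macrophage and efferocytosis lists, and Fcgr1 on the core list. The lists were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated per list, and with fry, which asks if a list moves on balance in 1 direction without comparing it with other genes. P-values of lists were adjusted over the 28 lists within a comparison. Of 196 camera tests, those of the gate marker list included, 109 passed, and 49 passed with an estimated correlation. Ly6c2 (a member of 2 lists), Hspa1b and Hbb-b1 had no matching probe.

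The genes named in the text were taken by a rule fixed before the data were examined. In each comparison it takes the gate markers, the 6 largest positive and 6 largest negative differences among genes past the threshold whose 4 values in one group all lay above the 4 in the other, and up to 3 members of each list with the largest differences past the threshold. Symbols of unnamed transcripts were left out. This gave 433 values of 143 genes, all of which entered the checks of stability and of single deviating arrays, and the text names fewer of them.

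Samples with the same replicate number were on average more alike than others after group means were removed. Their correlation across genes was at least 0.139, with a median of 0.342. Between different numbers the median was 0.298 within slides 1 and 3 or within slides 2 and 4, and -0.285 between these sides. The own number was the best match in 18 of 24 checks. Replicate numbers were taken to pair the arrays, although much of this likeness follows the sides. The main fit leaves this pairing out, so its SEs and p-values carry the differences between slides. The fit with replicate as a block is given where it changes a call or moves a count by more than 1.5 times. Alternatives fixed before the data were examined were normexp background correction of the raw signal with an offset of 50, quantile normalization, scaling to the median, no filter, a filter of 8 arrays, the mean over probes, a fit to the compared groups only, the replicate block, a mean-variance trend with robust eBayes, array weights, a 2-fold minimum, the value table under its own labels, and leaving out each array in turn. Fits to slides 1 and 3 or to slides 2 and 4 alone were added after the data were seen. With normexp the median difference of all genes from monocytes moved by -0.16 for CCR2+, -0.16 for MHCII-high and -0.17 for MHCII-low macrophages on the log2 scale. With median scaling it moved by -0.10 for MHCII-high macrophages.

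The gene-wise fit was tested on simulated data of the same size, with 200 of 21897 genes changed between CCR2+ and MHCII-high macrophages. limma recovered 14 of 67 genes changed 2-fold, 53 of 67 changed 4-fold and 57 of 66 changed 8-fold, with 2 false calls. With the replicate as a block it recovered 13, 51 and 55 of them, with 9 false calls. The simulated arrays were drawn independently, without the differences between slides that the real arrays show. The simulation therefore cannot judge the block on the real data. The package data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the tables and figures.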

Results

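The arrays compared 3 macrophage populations sorted from the hearts of untreated C57BL/6 mice with Ly6c-high monocytes from blood, 4 arrays per population and 16 in all. The sort parted the heart macrophages by CCR2, the chemokine receptor that draws monocytes out of bone marrow towards CCL2, and by MHCII, the molecules that show peptides to helper T cells. The purpose given for the series is gene expression in heart macrophages. Between 52.8% and 69.3% of the spots on an array were well above background. Differences are log2 values ± SE from limma, first group minus second, with n = 4 arrays per group and p-values adjusted over all genes tested. Unless stated otherwise, a named difference had its sign on 4 of 4 slides, each slide holding 1 array of every group.

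Transcripts of most sort markers followed the gates, which is a check of the labels and not a finding. Ccr2 was 14.6-fold higher in CCR2+ than in MHCII-high macrophages (log2 difference 3.87 ± 0.33, adjusted p = 2.24e-05). The MHCII genes H2-Ab1 (1.81 ± 0.25, adjusted p = 0.017), H2-Aa (1.67 ± 0.26, adjusted p = 0.0215) and H2-Eb1 (1.61 ± 0.23, adjusted p = 0.017) were higher in MHCII-high than in MHCII-low macrophages. Mertk was at least 36.8-fold higher in CCR2+, 53.1-fold in MHCII-high and 57.6-fold in MHCII-low macrophages than in monocytes. Ly6c1 was lower by -3.11 ± 0.28, -4.44 ± 0.28 and -4.32 ± 0.28 in the same order, on a probe that may also take the near-identical Ly6c2. All 3 macrophage gates excluded Ly6c. Yet Ly6c1 averaged 2.59 in CCR2+ macrophages, against 1.27 in MHCII-high and 1.39 in MHCII-low macrophages. Its difference between CCR2+ and MHCII-high macrophages passed the threshold, but leaving out some array ended that call. Itgax, which encodes CD11c, was higher in MHCII-high than in MHCII-low macrophages on 4 of 4 slides but missed the threshold (1.97 ± 0.55, adjusted p = 0.507). Fcgr1, which encodes CD64, did not differ past the threshold between any macrophage group and monocytes (0.32 ± 0.18, 0.25 ± 0.18 and 0.13 ± 0.18). Fcgr1 passed in CCR2+ macrophages with the replicate as a block (adjusted p = 0.246 without and 0.0429 with it), and with quantile normalization in CCR2+ (0.59, adjusted p = 0.0129) and MHCII-high macrophages (0.50, adjusted p = 0.0306). For CCR2+ macrophages the alternatives ran from that 0.0129 to 0.522 with an array left out. Of 15 checks on Ccr2, the 3 H2 genes, Itgax, Mertk and Ly6c1, 14 passed. This tally leaves out Fcgr1, and Ly6c1 between macrophage groups.

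**Figure D1:**
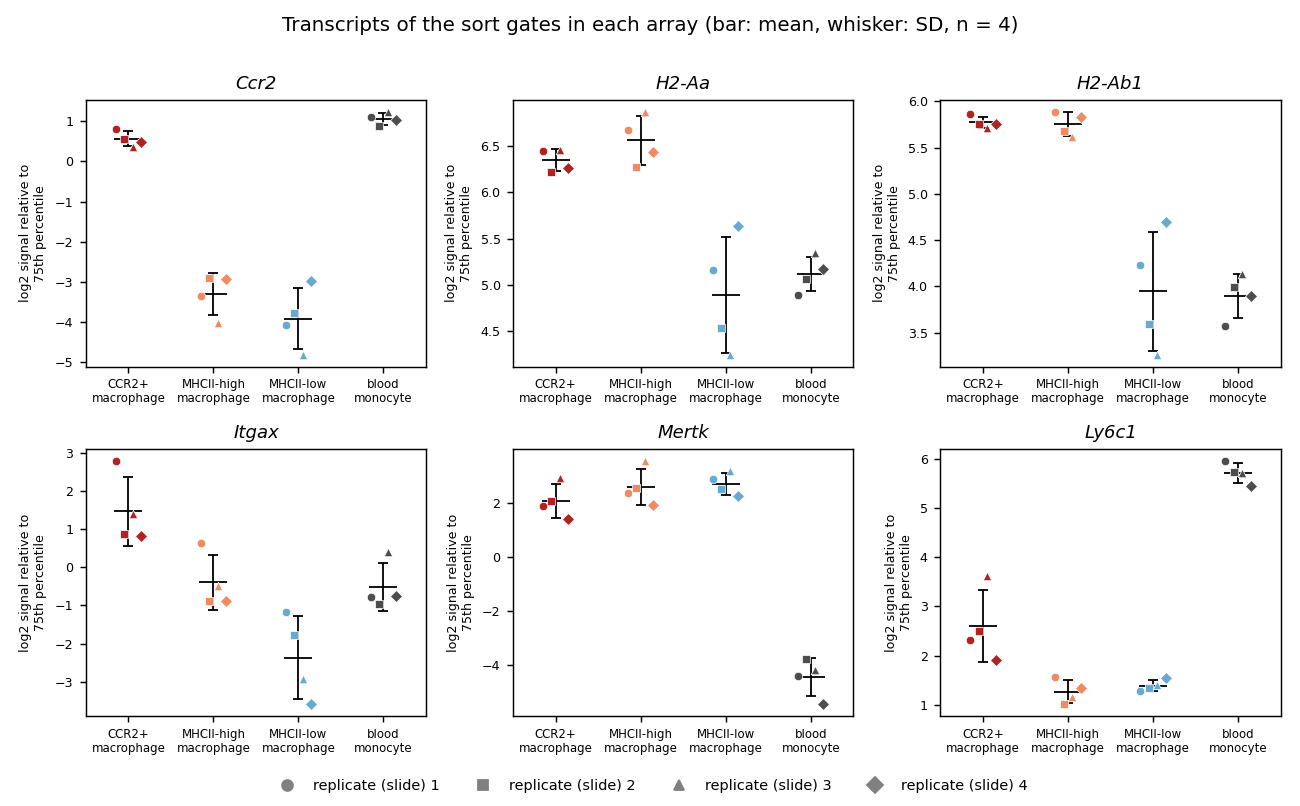
Log2 signal relative to the 75th percentile of the array (vertical axis) for 6 sort-gate transcripts in the 4 populations. Each symbol is 1 array and its shape gives the slide, bars are means and whiskers SD over 4 arrays. Ccr2 averaged 0.56 ± 0.18 in CCR2+ and -3.31 ± 0.53 in MHCII-high macrophages, and the 4 Mertk values of monocytes lie below all macrophage values.

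CCR2+ macrophages differed from MHCII-high macrophages, which carry MHCII but no CCR2, by more transcripts of a monocyte kind and fewer of a resident macrophage kind. Ear2, a ribonuclease of the eosinophil-associated family, was at least 31.7-fold higher in CCR2+ macrophages (adjusted p = 3.97e-10). The related Ear12 (4.62 ± 0.39, adjusted p = 2.24e-05) and Ear1 (3.71 ± 0.31, adjusted p = 2.24e-05) were higher too, although probes of such close relatives may take each other's transcripts. Fn1, the matrix protein fibronectin, was at least 31.4-fold higher (adjusted p = 2.24e-05). Spp1, the secreted matrix protein osteopontin, was not of the monocyte kind, as its probe was not well above background on any monocyte array. It was 15.5-fold higher in CCR2+ than in MHCII-high macrophages (3.96 ± 0.52, adjusted p = 0.000979), with slide differences from 2.82 to 6.48. In the other direction C6, a late complement component, was lower by -3.91 ± 0.50 (adjusted p = 0.000969). Timd4, a receptor for phosphatidylserine on dying cells, was 7.53-fold lower (-2.91 ± 0.25, adjusted p = 2.24e-05, slides from -3.86 to -2.19).

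Of 15 measured genes on the Ly6c-high monocyte list, 7 were higher in CCR2+ than in MHCII-high macrophages, 0 lower and 8 did not pass, and 9 were higher when adjusted over the list alone. Besides Ccr2, whose call was set by the gate, these included Plac8 (3.05 ± 0.56, adjusted p = 0.0116) and the chitinase-like Chil3 (2.86 ± 0.66, adjusted p = 0.0461, or 0.0589 with the replicate as a block). Over the CCR2+ arrays Plac8 (-0.90 to 2.73) and Ly6c1 (1.92 to 3.63) were both lowest on replicate 4 and highest on replicate 3. Ccr2 was instead lowest on replicate 3 (0.37) and highest on replicate 1 (0.81). The list median was 1.30, or 1.11 with dim genes at their bound, and ran from 0.58 to 2.47 by slide (camera adjusted p = 5.39e-15, and 0.00398 with an estimated correlation). Of 20 resident macrophage genes 14 were lower, 0 higher and 6 did not pass, and all 20 were lower when adjusted over the list alone. Fcna, a lectin that starts complement (-2.45 ± 0.33, adjusted p = 0.00124), and Vsig4, a complement receptor (-2.33 ± 0.47, adjusted p = 0.022), were among them. Their median was -1.47, from -1.81 to -0.97 by slide (camera adjusted p = 1.07e-35, and 0.00076 with an estimated correlation). Both lists draw on published heart macrophage work, possibly on these samples, and are not independent evidence.

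The alternative activation list, genes that interleukin-4 or resident state raises in macrophages, had 4 members lower, 2 higher and 6 not past the threshold, with 5 lower and 2 higher when adjusted over the list alone. The scavenger receptor Cd163 (-2.15 ± 0.22, adjusted p = 9.33e-05) and the eosinophil chemoattractant Ccl24 (-2.05 ± 0.29, adjusted p = 0.00164) were lower, and both are also on the resident macrophage list. The list median was -0.51 (camera adjusted p = 8e-04, and 0.0203 with an estimated correlation). Complement genes had 4 lower, 0 higher and 14 not past the threshold (4 lower when adjusted over the list alone), with C2 (-2.57 ± 0.27, adjusted p = 0.000126) and C4b (-2.36 ± 0.33, adjusted p = 0.00143) as examples. The complement list passed camera (adjusted p = 0.000142, median -0.30) but not with an estimated correlation (adjusted p = 0.0777 with an estimated correlation). Of 21 efferocytosis and scavenger genes, which serve the uptake of dead cells, 4 were lower, 0 higher and 17 not past the threshold, and 5 were lower when adjusted over the list alone. Gas6, the ligand that bridges dying cells to MerTK and a member of the resident macrophage list too, was one of them (-1.22 ± 0.21, adjusted p = 0.00766). This list had a median of -0.14 (camera adjusted p = 0.00277, but adjusted p = 0.273 with an estimated correlation).

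Myeloid transcription factors had 2 members higher, 1 lower and 20 not past the threshold, with 5 higher and 1 lower when adjusted over the list alone. The basic helix-loop-helix factor Bhlhe40 (2.83 ± 0.38, adjusted p = 0.00115) and the leucine zipper factor Nfil3 (1.94 ± 0.31, adjusted p = 0.00469) were higher, and Spic, a factor of iron-recycling macrophages, was lower (-0.96 ± 0.21, adjusted p = 0.0359). The list median was 0.06 (camera adjusted p = 0.014, but adjusted p = 0.277 with an estimated correlation). Of 16 inflammasome and interleukin-1 genes 2 were higher, 0 lower and 14 not past the threshold, also 2 when adjusted over the list alone. They were Mefv, which encodes the sensor pyrin (2.17 ± 0.28, adjusted p = 0.000979), and the interleukin-1 receptor antagonist Il1rn (1.43 ± 0.29, adjusted p = 0.0201). The inflammasome list itself did not pass camera (median 0.30, adjusted p = 0.0552). Clec4e, a receptor for mycobacterial glycolipid, was at least 3.33-fold higher (adjusted p = 4.5e-05) and was the 1 member of 19 pattern recognition genes past the threshold. That list did not pass either (median 0.19, camera adjusted p = 0.201).

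Markers of other cells were measured beside these. The dendritic cell list had 3 members higher, 0 lower and 13 not past the threshold, among them the protease Dpp4, well above background on 2 of 4 MHCII-high arrays (1.84 ± 0.30, adjusted p = 0.0054), and the chemokine Ccl17 (1.81 ± 0.38, adjusted p = 0.0257). Its median of -0.04 and mean of 0.35 differed in sign and camera, pointing up, did not pass (adjusted p = 0.149). Adjusted over the list alone, 3 were higher and 1 lower. In the cardiomyocyte list no single gene passed, and the median was -0.39 (camera adjusted p = 0.000228, but adjusted p = 0.13 with an estimated correlation). The endothelial list had a median of 0.48 with no single gene past the threshold (camera adjusted p = 0.00153, but adjusted p = 0.214 with an estimated correlation).

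limma called 273 of 21897 genes different between CCR2+ and MHCII-high macrophages, 139 higher and 134 lower, and 549 with the replicate as a block (275 higher, 274 lower). The count was 160 without CCR2+ replicate 1, 153 without CCR2+ replicate 2 and 166 without MHCII-high replicate 3, 172 with median scaling and 932 with array weights, and it was 34 in slides 2 and 4 alone and 2 in slides 1 and 3 alone, with fewer arrays.

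**Figure D2:**
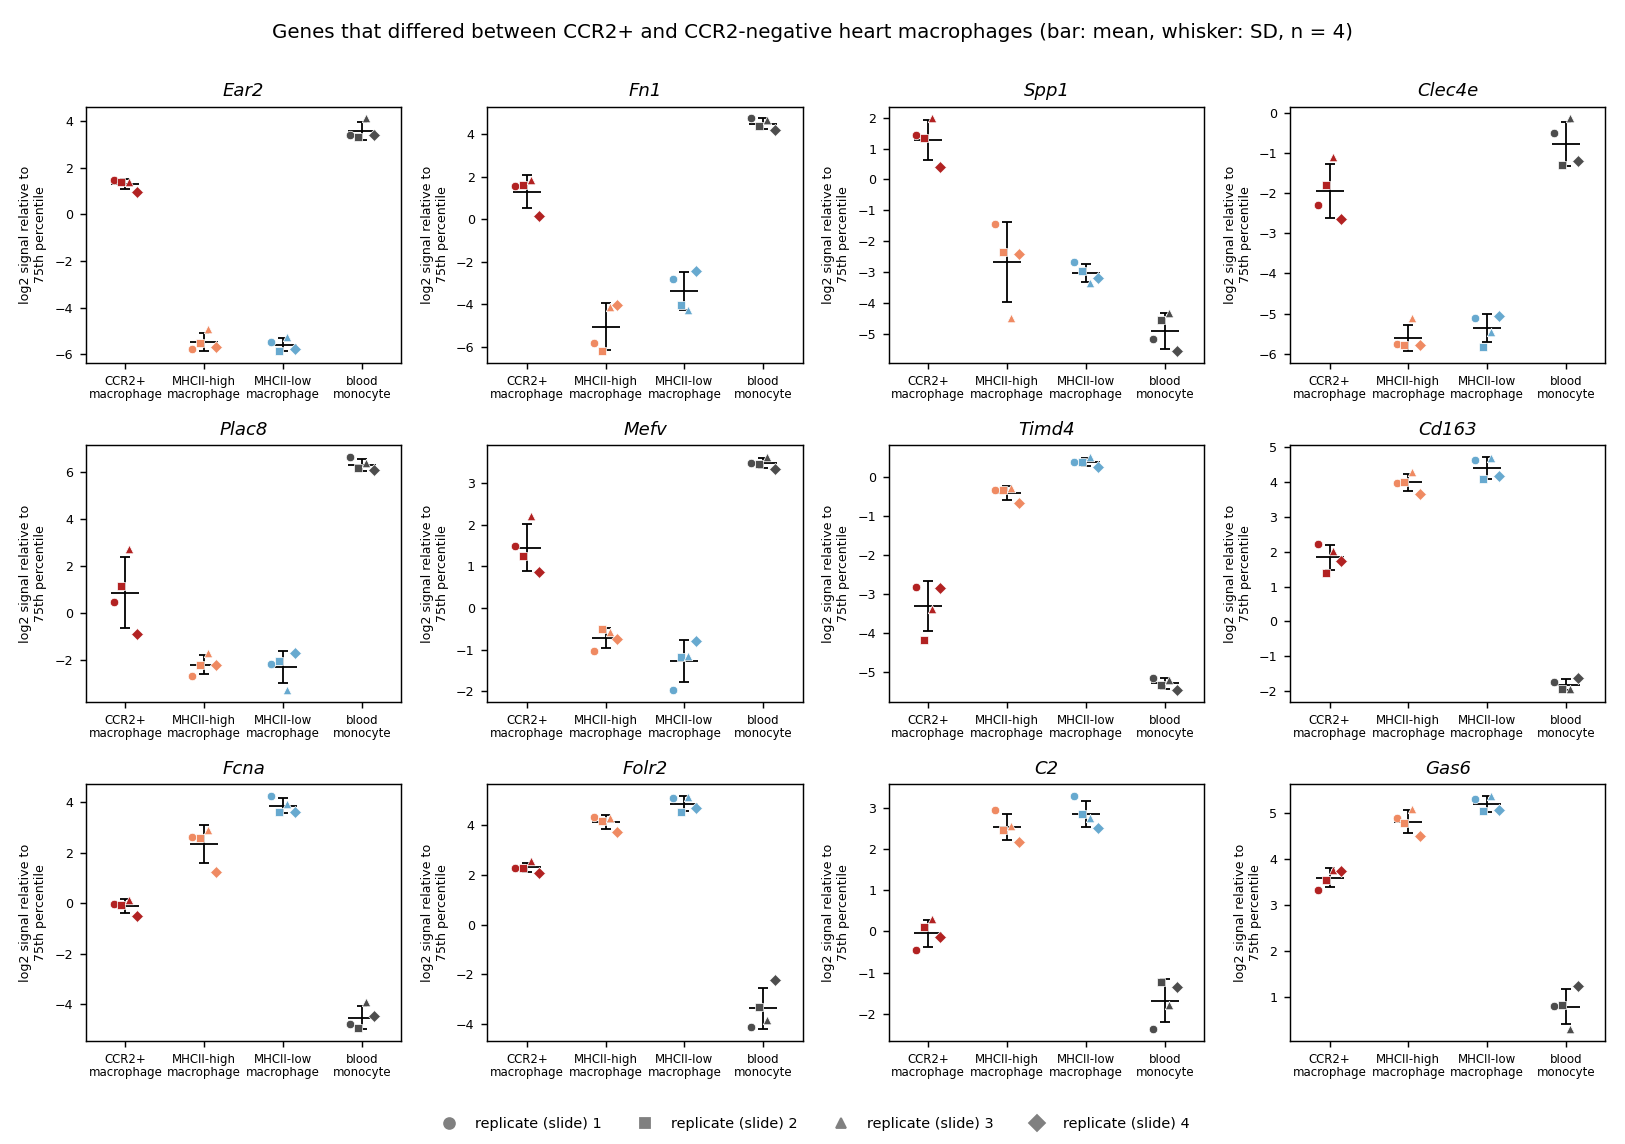
Log2 signal relative to the 75th percentile of the array (vertical axis) for 12 genes that differed between CCR2+ and CCR2-negative heart macrophages, in all 4 populations. Symbols are arrays with the slide given by shape, bars are means and whiskers SD over 4 arrays. Ear2 averaged 1.31 ± 0.23 in CCR2+ macrophages and 3.57 ± 0.38 in monocytes, and Timd4 averaged -3.31 ± 0.64 in CCR2+ and -0.40 ± 0.18 in MHCII-high macrophages.

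CCR2+ macrophages differed from MHCII-low macrophages, which carry neither CCR2 nor much MHCII, in 607 genes. Ear2 was at least 32.1-fold higher in CCR2+ macrophages (adjusted p = 3.07e-10), and Fn1 (4.68 ± 0.54, adjusted p = 0.000119) and Ccr2 (4.47 ± 0.33, adjusted p = 1.55e-06) were higher. Map4k1, a kinase of blood cells (5.12 ± 0.41, adjusted p = 4.47e-06), the aspartic protease Napsa (4.61 ± 0.53, adjusted p = 0.000121) and the macrophage elastase Mmp12 (4.38 ± 0.42, adjusted p = 2.12e-05) were higher. Lower were Fcna (-3.97 ± 0.33, adjusted p = 6.73e-06), Vsig4 (-3.95 ± 0.47, adjusted p = 0.000161), the endothelin receptor Ednrb (-3.81 ± 0.44, adjusted p = 0.000121) and Timd4 (-3.70 ± 0.25, adjusted p = 9.51e-07). In MHCII-low macrophages Ccr2 and Map4k1 were well above background on 1 of 4 arrays and Fn1 and Napsa on 2 of 4, so the size of these differences is uncertain.

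Of 16 MHC class II presentation genes 9 were higher, 0 lower and 7 not past the threshold, and 10 were higher when adjusted over the list alone. H2-DMb2, a chain of the H2-DM molecule that helps to load peptides onto MHCII (2.86 ± 0.40, adjusted p = 0.000558), and H2-Ab1 (1.83 ± 0.25, adjusted p = 0.00061) were examples. The median was 1.07, from 0.47 to 1.21 by slide (camera adjusted p = 8.05e-13, and 0.00534 with an estimated correlation). This list shares its H2 genes with the gate. In CCR2+ against MHCII-high macrophages the same list had 1 member higher, 0 lower and 15 not past the threshold, also 1 when adjusted over the list alone, and did not pass camera (median 0.01, adjusted p = 0.527). The 1 gene was H2-DMb2 (1.91 ± 0.40, adjusted p = 0.0252), whose call was lost without CCR2+ replicate 1 or 4 or MHCII-high replicate 2, 3 or 4, and with median scaling (adjusted p = 0.0696). Of the 9 gate markers, 7 were higher, 0 lower and 2 not past the threshold, with 7 higher also when adjusted over the list alone (camera adjusted p = 1.7e-13, and 0.00437 with an estimated correlation). Itgax was among them (3.83 ± 0.55, adjusted p = 0.000804).

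Resident macrophage genes were lower for 19 of 20 members, with 0 higher and 1 not past the threshold, and for all 20 when adjusted over the list alone. The median was -2.40, from -2.63 to -1.91 by slide (camera adjusted p = 7.04e-47, and 0.000197 with an estimated correlation), and the folate receptor Folr2 was an example (-2.57 ± 0.33, adjusted p = 0.000278). Ly6c-high monocyte genes were higher for 6 of 15, lower for 0 and not past the threshold for 9, with 7 higher when adjusted over the list alone (median 1.01, or 0.89 with dim genes at their bound, camera adjusted p = 7.11e-09, and 0.0145 with an estimated correlation). Plac8 was one (3.16 ± 0.56, adjusted p = 0.00456). Complement genes were lower for 4 of 18, with 0 higher and 14 not past the threshold, and 5 lower and 1 higher when adjusted over the list alone (median -0.46, camera adjusted p = 5.39e-07, and 0.0156 with an estimated correlation). C2 was among them (-2.90 ± 0.27, adjusted p = 1.81e-05). Alternative activation genes were lower for 5, higher for 2 and not past the threshold for 5, with 6 lower and 2 higher when adjusted over the list alone (median -0.66, camera adjusted p = 0.000287, and 0.0104 with an estimated correlation). Ccl24 (-2.95 ± 0.29, adjusted p = 2.7e-05) and Cd163 (-2.56 ± 0.22, adjusted p = 7.55e-06) were lower.

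Inflammasome genes were higher for 5 of 16, lower for 0 and not past the threshold for 11, with 5 also when adjusted over the list alone (median 0.18, camera adjusted p = 0.00425, but adjusted p = 0.218 with an estimated correlation). They included Mefv (2.72 ± 0.28, adjusted p = 4.93e-05) and Il1b, the cytokine interleukin-1 beta (1.83 ± 0.21, adjusted p = 0.000119). Growth factor and matrix genes moved both ways, with 5 higher, 4 lower and 13 not past the threshold, and 7 higher and 5 lower when adjusted over the list alone. Mmp12, Fn1 and Spp1 (4.33 ± 0.52, adjusted p = 0.000161) were higher, and the list had a median of 0.01 (camera adjusted p = 0.2). The transcription factor Runx3 was higher (1.34 ± 0.22, adjusted p = 0.00214). Dendritic cell genes, measured beside these, were higher for 4 of 16, lower for 0 and not past the threshold for 12, with 5 higher when adjusted over the list alone (median 0.17, camera adjusted p = 0.00809, but adjusted p = 0.0574 with an estimated correlation). The neutrophil list had 1 member lower, Mmp9, a gelatinase, by at least 3.64-fold (adjusted p = 0.000532), 0 higher and 10 not past the threshold, and did not pass camera (median -0.37, adjusted p = 0.156). No single endothelial or cardiomyocyte gene passed. The endothelial list had a median of 0.47, from 0.29 to 0.35 for the medians by slide (camera adjusted p = 0.0113, but adjusted p = 0.285 with an estimated correlation). The cardiomyocyte list had a median of -0.32, from -0.33 to -0.21 by slide (camera adjusted p = 0.0252, but adjusted p = 0.309 with an estimated correlation and 0.052 with normexp).

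limma called 607 of 21897 genes different between CCR2+ and MHCII-low macrophages, 325 higher and 282 lower, and 1253 with the replicate as a block (617 higher, 636 lower). The count was 377 with median scaling, 330 in a fit to these 2 groups only and 1204 with array weights, and it was 305 in slides 2 and 4 alone and 67 in slides 1 and 3 alone.

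MHCII-high and MHCII-low macrophages, both without CCR2, differed in few genes past the threshold of the main fit, 15, against 77 with the replicate as a block. Higher in MHCII-high macrophages were H2-Ab1, H2-Aa and H2-Eb1, as given above, Il1b by 2.68-fold (1.42 ± 0.21, adjusted p = 0.017), the organic anion carrier Slco4a1 (2.12 ± 0.35, adjusted p = 0.0322) and Cps1, an enzyme of the urea cycle (1.96 ± 0.28, adjusted p = 0.017). Lower were the scavenger receptor Colec12 (-2.49 ± 0.30, adjusted p = 0.0113, slides from -3.76 to -1.39), Pimreg, a gene of dividing cells (-2.27 ± 0.35, adjusted p = 0.0199), Rgs7bp, which binds regulators of G protein signalling (-2.24 ± 0.33, adjusted p = 0.017), and Gypc, a membrane glycoprotein of red cells (-1.73 ± 0.28, adjusted p = 0.0313). H2-DMb1 was also higher (1.58 ± 0.21, adjusted p = 0.017), but its 2 kept probes did not move alike. Colec12 and Pimreg were well above background on 1 of 4 MHCII-high arrays, so the size of their differences is uncertain.

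Of 16 MHC class II genes 6 were higher in MHCII-high than in MHCII-low macrophages, 0 lower and 10 not past the threshold, and 8 were higher when adjusted over the list alone. Their median was 0.85, from 0.56 to 1.13 by slide (camera adjusted p = 7.39e-22, and 0.00131 with an estimated correlation). Resident macrophage genes as a list were lower in MHCII-high macrophages, with a median of -0.64, from -0.84 to -0.43 by slide (camera adjusted p = 9.95e-21, and 0.00476 with an estimated correlation). None of the 20 passed over all genes in limma and 9 were lower when adjusted over the list alone, or 2 over all genes with the replicate as a block. Core macrophage genes had 0 of 19 past the threshold, with 1 lower when adjusted over the list alone, and a median of -0.24 (camera adjusted p = 0.000601, but adjusted p = 0.367 with an estimated correlation). Cell cycle genes had a median of -0.28 with 0 of 25 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.00115, but adjusted p = 0.369 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.16 with 0 of 27 past the threshold (camera adjusted p = 0.000572, but adjusted p = 0.744 with an estimated correlation).

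limma called 15 of 21897 genes different between the CCR2-negative groups, 11 higher and 4 lower (857 at an unadjusted p under 0.05), and 77 with the replicate as a block (50 higher, 27 lower). With normexp the split was 15 higher and 2 lower. The count was 4 with median scaling and 0 in a limma fit to these 2 groups only (758 at an unadjusted p under 0.05), and it was 2 in slides 2 and 4 alone and 0 in slides 1 and 3 alone (943 unadjusted in limma). It was 0 without MHCII-low replicate 2 (1011 unadjusted) or 3 (662 unadjusted), 2, 8 and 4 without MHCII-high replicates 1, 3 and 4, and each gene named here lost its call in at least 1 such fit. All unadjusted counts in this paragraph lie below a share of 0.05 of the genes, which chance alone would give. By themselves they do not point to further differences.

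Heart macrophages of all 3 groups differed widely from blood monocytes, in a comparison that joins a change of tissue with one of cell type. In the mean of the macrophage groups the complement subunit genes C1qc, by at least 228-fold (adjusted p = 1.79e-15), and C1qa, by 319-fold (8.32 ± 0.20, adjusted p = 4.78e-13), were higher. So were the tetraspanin Cd81, by at least 132-fold (adjusted p = 7.2e-12), Folr2 (7.14 ± 0.27, adjusted p = 2.48e-11) and the scavenger receptor Stab1 (7.10 ± 0.20, adjusted p = 2.54e-12). Lower were Plac8 by 182-fold (-7.51 ± 0.46, adjusted p = 6.03e-09), Chil3 (-7.06 ± 0.54, adjusted p = 7.5e-08) and haptoglobin, Hp (-6.66 ± 0.37, adjusted p = 1.99e-09). Among the named genes whose probe was at times dim in monocytes, Folr2, Ccl8 and Ccl4 were well above background there on 1 of 4 arrays and Stab1 and Egr1 on 2 of 4, so the size of their differences is uncertain. Each gene named for this mean had its sign on 4 of 4 slides in each of the 3 pairs, and each gene named for a single pair had it on 4 of 4 slides there unless another value is given.

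Of 20 resident macrophage genes 19 were higher than in monocytes, 0 lower and 1 not past the threshold, also 19 when adjusted over the list alone (median 5.21, or 4.55 with dim genes at their bound, camera adjusted p = 4.52e-30, and 0.000858 with an estimated correlation). All 15 Ly6c-high monocyte genes were lower, also when adjusted over the list alone (median -3.95, camera adjusted p = 1.19e-17, and 0.00135 with an estimated correlation). Complement genes were higher for 13 of 18, lower for 3 and not past the threshold for 2, the same counts as when adjusted over the list alone (median 2.59, or 1.95 with dim genes at their bound, camera adjusted p = 2.01e-10, and 0.00402 with an estimated correlation). Alternative activation genes were higher for 9, lower for 1, Chil3, and not past the threshold for 2, with 10 higher and 1 lower when adjusted over the list alone (median 2.87, camera adjusted p = 3.21e-10, and 0.00051 with an estimated correlation). Core macrophage genes were higher for 10 of 19, lower for 1 and not past the threshold for 8, with 11 higher and 2 lower when adjusted over the list alone. Among them were the mannose receptor Mrc1, by at least 31.0-fold (adjusted p = 1.91e-11), and the lipopolysaccharide co-receptor Cd14 (3.56 ± 0.34, adjusted p = 9.92e-07). The core list passed camera (median 1.02, adjusted p = 2.24e-07) but not with an estimated correlation (adjusted p = 0.0614 with an estimated correlation). Efferocytosis genes were higher for 9 of 21, lower for 2 and not past the threshold for 10, with 10 higher and 3 lower when adjusted over the list alone. Their median was 0.60 (camera adjusted p = 8.22e-06, but adjusted p = 0.0614 with an estimated correlation), and Cd163 was an example (5.23 ± 0.18, adjusted p = 9.12e-12).

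Inflammatory cytokine and chemokine genes were higher in macrophages for 14 of 20, lower for 1 and not past the threshold for 5, with 15 higher and 1 lower when adjusted over the list alone. The chemokine Cxcl16 was at least 54.5-fold higher (adjusted p = 1.2e-11), Ccl8 was higher by 6.36 ± 0.51 (adjusted p = 1.44e-07) and Ccl4 by 6.25 ± 0.40 (adjusted p = 1.23e-08). The list median was 2.41, or 1.54 with dim genes at their bound (camera adjusted p = 1.42e-12, and 0.0134 with an estimated correlation). Immediate early and stress genes, which tissue digestion is known to induce, were higher for 21 of 24, lower for 1 and not past the threshold for 2, with the same counts when adjusted over the list alone. The heat shock gene Hspa1a (5.89 ± 0.26, adjusted p = 1.6e-10) and the early response factors Egr1 (5.61 ± 0.21, adjusted p = 2.37e-11) and Fosb (4.95 ± 0.17, adjusted p = 9.12e-12) were examples. Their median was 2.40 (camera adjusted p = 4.8e-22, and 0.0242 with an estimated correlation), and the digestion text of the labels, which names cardiac tissue, stands on the monocyte samples too, with none given for blood. Growth factor and matrix genes were higher for 16 of 22, lower for 2, including Fn1 by at least 85.3-fold (adjusted p = 1.06e-08), and not past the threshold for 4, with the same counts when adjusted over the list alone (median 2.11, or 1.05 with dim genes at their bound, camera adjusted p = 5.47e-10, and 0.0162 with an estimated correlation). The platelet-derived growth factor gene Pdgfa was higher by 4.66 ± 0.18 (adjusted p = 3.59e-11). Cell cycle genes were higher for 15 of 25, lower for 0 and not past the threshold for 10, with 17 higher when adjusted over the list alone (median 1.18, or 1.03 with dim genes at their bound, camera adjusted p = 2.22e-10, and 0.0269 with an estimated correlation). The ubiquitin-conjugating enzyme of mitosis Ube2c was an example (3.41 ± 0.17, adjusted p = 8.06e-10).

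Transcripts of other heart and blood cells moved with the same comparison. Cardiomyocyte genes were higher in the macrophages for 13 of 15, lower for 0 and not past the threshold for 2, also 13 when adjusted over the list alone (median 2.80, or 2.50 with dim genes at their bound, from 2.40 to 3.21 by slide, camera adjusted p = 1.87e-13, and 0.00402 with an estimated correlation). Myoglobin, Mb, was at least 30.8-fold higher (adjusted p = 3.64e-12), the troponin Tnnt2 at least 17.9-fold (adjusted p = 2.98e-11), and the myosin light chain Myl3 was higher by 3.79 ± 0.25 (adjusted p = 1.87e-08). Fibroblast and mural genes were higher for 6 of 9, lower for 0 and not past the threshold for 3, also 6 when adjusted over the list alone. The matrix proteoglycan decorin, Dcn, was at least 32.2-fold higher (adjusted p = 6.36e-11), and the list median was 1.57, or 0.80 with dim genes at their bound (camera adjusted p = 0.00027, but adjusted p = 0.0598 with an estimated correlation). Endothelial genes were higher for 6 of 12, lower for 1 and not past the threshold for 5, with 7 higher and 1 lower when adjusted over the list alone (median 0.99, camera adjusted p = 0.00243, but adjusted p = 0.194 with an estimated correlation). Erythroid and platelet genes were lower for 4 of 9, higher for 0 and not past the threshold for 5, also 4 when adjusted over the list alone. The haemoglobin gene Hba-a1 was lower by -5.56 ± 0.49 (adjusted p = 4.46e-07), on a probe that may also take its near-identical copy. The erythroid list had a median of -0.48 and passed camera (adjusted p = 0.0291), but not with an estimated correlation (adjusted p = 0.31 with an estimated correlation) nor with the replicate as a block (adjusted p = 0.0901).

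limma called 5990 of 21897 genes different between the mean of the macrophage groups and monocytes, 2720 higher and 3270 lower, a share of 45.4% higher. With normexp it called 6797, with 1999 higher and 4798 lower, a share of 29.4% higher, and with quantile normalization 6005, with 3057 higher and 2948 lower, a share of 50.9% higher. With a 2-fold minimum 1765 were higher and 1284 lower. The side with more calls thus depends on the processing, for the mean and for each of the 3 pairs. The count was 2933 in slides 1 and 3 alone, 3049 with a 2-fold minimum and 9616 without a filter.

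CCR2+ macrophages and monocytes had Ccr2 at levels that did not differ past the threshold (-0.49 ± 0.33, adjusted p = 0.328, lower on 4 of 4 slides), and CCR2+ macrophages had more of most listed resident and complement transcripts. C1qc was at least 187-fold higher (adjusted p = 5.84e-14), Mmp12 at least 105-fold (adjusted p = 9.14e-09) and Stab1 was higher by 6.16 ± 0.25 (adjusted p = 2.83e-10). Lower were the interferon-induced membrane protein gene Ifitm6, well above background on 2 of 4 CCR2+ arrays (-6.14 ± 0.57, adjusted p = 1.58e-06), and S1pr5, a receptor for sphingosine phosphate (-5.50 ± 0.68, adjusted p = 3.24e-05). Resident macrophage genes were higher for 18 of 20, lower for 1 and not past the threshold for 1, the same as when adjusted over the list alone (median 3.54, or 2.91 with dim genes at their bound, camera adjusted p = 1.13e-23, and 0.00268 with an estimated correlation). Ly6c-high monocyte genes were lower for 14 of 15 and not past the threshold for 1, also 14 when adjusted over the list alone (median -3.11, camera adjusted p = 1.31e-14, and 0.00324 with an estimated correlation). Complement genes were higher for 13 of 18, lower for 3 and not past the threshold for 2, the same as when adjusted over the list alone (median 1.46, or 1.24 with dim genes at their bound, camera adjusted p = 1.41e-09, and 0.00618 with an estimated correlation). Il1b (3.06 ± 0.21, adjusted p = 5.9e-08) and H2-Ab1 (1.87 ± 0.25, adjusted p = 7.84e-05) were higher, and Mefv was lower (-2.02 ± 0.28, adjusted p = 0.000103). Cardiomyocyte genes were higher for 11 of 15, with 0 lower and 4 not past the threshold (11 when adjusted over the list alone), as Mb by at least 25.6-fold (adjusted p = 1.79e-10). limma called 4744 genes, 2182 higher and 2562 lower (46.0% higher), 5175 with normexp, 1551 higher and 3624 lower (30.0% higher), and 4576 with quantile normalization, 2498 higher and 2078 lower (54.6% higher). The count was 7394 with the replicate as a block (3123 higher, 4271 lower), 8465 without a filter and 1467 in slides 1 and 3 alone.

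MHCII-high macrophages differed from monocytes in Ccr2 (-4.36 ± 0.33, adjusted p = 9.71e-08) as the gate sets it, and in resident genes. Folr2 was higher by 7.51 ± 0.33 (adjusted p = 2.51e-10), Stab1 by 7.36 ± 0.25 (adjusted p = 2.85e-11) and Cd163 by 5.81 ± 0.22 (adjusted p = 6.45e-11). Lower were Fn1 by at least 288-fold (adjusted p = 4.5e-09), Ear2 by at least 152-fold (adjusted p = 1.82e-12), Plac8 (-8.49 ± 0.56, adjusted p = 2.39e-08) and Napsa (-7.22 ± 0.53, adjusted p = 8.28e-08). Resident macrophage genes were higher for 19 of 20, lower for 0 and not past the threshold for 1, and all 20 were higher when adjusted over the list alone (median 5.33, or 4.80 with dim genes at their bound, camera adjusted p = 6.22e-34, and 0.000485 with an estimated correlation). H2-Ab1 was higher by 1.86 ± 0.25 (adjusted p = 6.4e-05), and MHC class II genes were higher for 8 of 16, lower for 1 and not past the threshold for 7, with 8 higher and 2 lower when adjusted over the list alone (median 0.47, camera adjusted p = 0.00981, but adjusted p = 0.234 with an estimated correlation). Cardiomyocyte genes were higher for 13 of 15, lower for 0 and not past the threshold for 2, also 13 when adjusted over the list alone. limma called 4686 genes, 2199 higher and 2487 lower (46.9% higher), 4312 with normexp, 1536 higher and 2776 lower (35.6% higher), and 4533 with quantile normalization, 2370 higher and 2163 lower (52.3% higher). The count was 2998 with a 2-fold minimum and 1785 in slides 1 and 3 alone.

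MHCII-low macrophages had more of all 20 listed resident transcripts than monocytes, and their class II genes moved both ways. Fcna was at least 127-fold higher (adjusted p = 8.25e-11), Folr2 was higher by 8.24 ± 0.33 (adjusted p = 8.25e-11) and Stab1 by 7.79 ± 0.25 (adjusted p = 1.72e-11). The resident genes were all higher also when adjusted over the list alone (median 6.42, or 5.53 with dim genes at their bound, camera adjusted p = 2.91e-37, and 0.000308 with an estimated correlation). H2-Ab1 (0.05 ± 0.25, adjusted p = 0.937), H2-Aa (-0.22 ± 0.26, adjusted p = 0.649) and H2-Eb1 (0.51 ± 0.23, adjusted p = 0.146) each had 2 of 4 slides on either side of 0, and H2-Eb1 passed with normexp (adjusted p = 0.0304) and quantile normalization (adjusted p = 0.0133), with up to 0.394 when an array was left out. H2-DMb2 was lower (-1.74 ± 0.40, adjusted p = 0.00446). Of 16 MHC class II genes 5 were lower, 1 higher and 10 not past the threshold, the same as when adjusted over the list alone. The class II list, lower on 4 of 4 slides, did not pass camera (median -0.39, from -0.62 to -0.07 by slide, adjusted p = 0.177). Lower were Plac8 (-8.59 ± 0.56, adjusted p = 1.94e-08), Napsa (-8.31 ± 0.53, adjusted p = 1.6e-08), Fn1 (-7.88 ± 0.54, adjusted p = 3.27e-08) and Mefv (-4.75 ± 0.28, adjusted p = 7.59e-09), with Napsa and Fn1 well above background on 2 of 4 MHCII-low arrays. Cardiomyocyte genes were higher for 11 of 15, lower for 0 and not past the threshold for 4, with 12 higher when adjusted over the list alone. limma called 4660 genes, 2212 higher and 2448 lower (47.5% higher), 4785 with normexp, 1623 higher and 3162 lower (33.9% higher), and 4655 with quantile normalization, 2372 higher and 2283 lower (51.0% higher). The count was 7050 with the replicate as a block (3083 higher, 3967 lower), 3025 with a 2-fold minimum and 1858 in slides 1 and 3 alone.

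**Figure D3:**
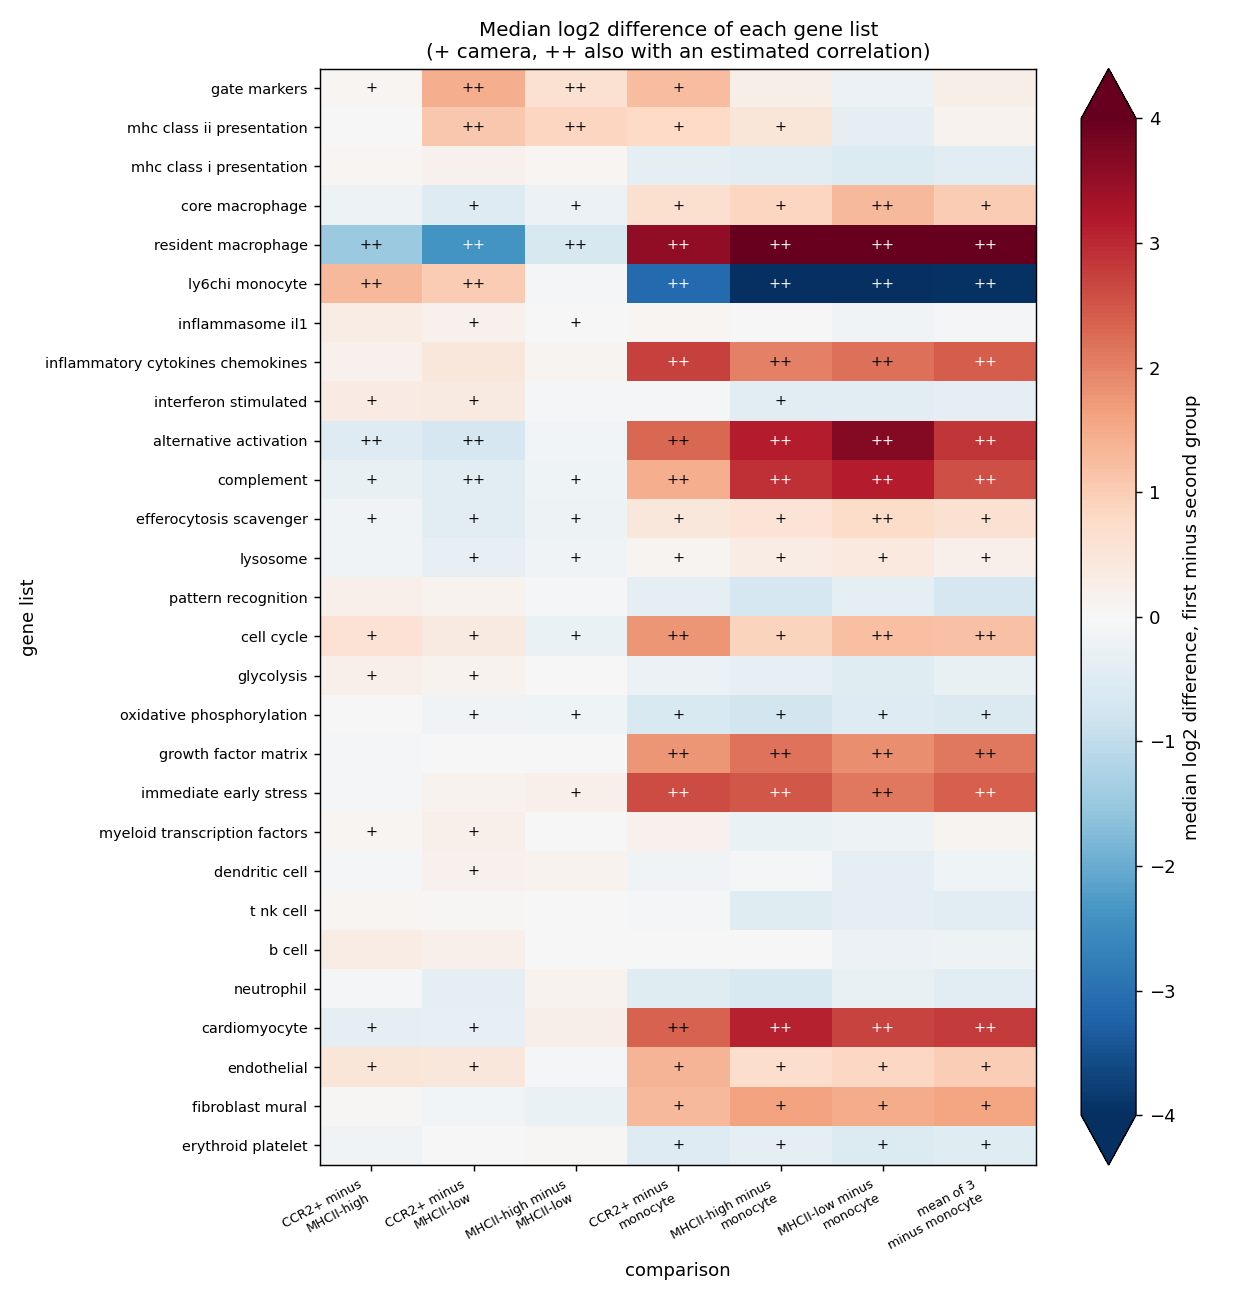
Median log2 difference (colour, clipped at 4 and -4) of the 28 gene lists (vertical axis) in the 7 comparisons (horizontal axis). A single plus marks lists past the camera threshold and a double plus those that also pass with an estimated correlation. The resident macrophage list runs from a median of -2.40 in CCR2+ minus MHCII-low macrophages to 6.42 (5.53 with dim genes at their bound) in MHCII-low macrophages minus monocytes.

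The arrays also differed along the slides within every group. The first principal component, 35.1% of the variance, parted monocytes from macrophages, and the second, 23.7%, placed arrays of slides 2 and 4 apart from those of slides 1 and 3 in each group. Each group had 2 arrays on either side, so the split does not coincide with a group. Slides 1 and 3 were not alike in the macrophage groups, where slide 1 lay furthest out. For MHCII-low macrophages the second component was -85.2 on slide 1 and 4.2 on slide 3, against 65.3 and 52.2 on slides 2 and 4.

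**Figure D4:**
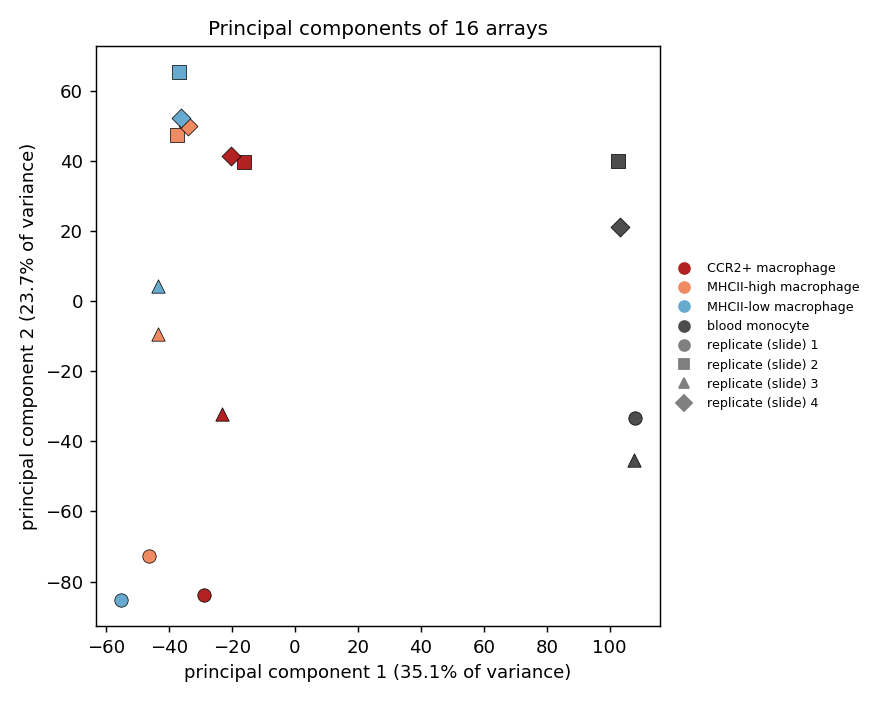
The 16 arrays on the first (horizontal, 35.1% of variance) and second (vertical, 23.7%) principal components of the log2 signals. Colour gives the population and symbol the slide. Monocyte arrays lie apart from macrophage arrays on the horizontal axis, and within each population the arrays of slides 2 and 4 lie above those of slides 1 and 3.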

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

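The tests of the signal distribution of the arrays, of tissue digestion, of dimmer monocyte arrays, of scanner files under wrong labels and of relabelling within slides were chosen after the result was seen, and the other tests in this part before. Single arrays that lay far from the other 3 of their group were looked for by the gap to the nearest array over the whole range of the group. Chance passes the limit in about 1 in 20 groups. Of 530 combinations of a named gene and a group 38 passed it (7.17%), and of 20 combinations of an array quality value and a group 1 did.

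Among CCR2+ macrophages the gap took this share of the range for Cxcl16 on replicate 1 (0.851), for C1qa (0.959), Hspa1a (0.887), S1pr5 (0.937) and Tie1 (0.899) on replicate 3, and for Fn1 on replicate 4 (0.836). Among MHCII-high macrophages it did so for C6 (0.872), Ctsf (0.968), Mcm2 (0.898), Ndufb5 (0.855) and Psme1 (0.873) on replicate 1, for Runx3 (0.941) and Tnnt2 (0.945) on replicate 2, for Chil3 (0.839) and Slc2a1 (0.870) on replicate 3, and for Rgs7bp (0.878) and Timd4 (0.844) on replicate 4. Among MHCII-low macrophages the genes were Birc5 (0.830), Ccl17 (0.863), Dpp4 (0.971) and Maf (0.884) on replicate 1, Mmp8 on replicate 2 (0.845) and Ear12 on replicate 4 (0.847). Among monocytes they were Alas2 (0.835), Cd177 (0.885), Gsdmd (0.902), Mcm2 (0.889), Pgk1 (0.854), Pla2g2d (0.874) and Zbp1 (0.937) on replicate 1, Dpp4 (0.845) and Tnfrsf25 (0.924) on replicate 2, Ear2 (0.884), Itgax (0.840), Lgmn (0.835) and Ube2c (0.889) on replicate 3, and Mmp8 (0.882) and Psmb10 (0.843) on replicate 4. The 1 quality value was the share of spots marked as non-uniform or deviating on MHCII-low replicate 1 (0.866).

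Control spots outside the comparisons also gave signal. Of 10 control probes for E1A, 8 lay above almost all negative control spots on each of the 16 arrays, and so did 4 of 12 probes for ERCC standards. No amounts of added control RNA are given in the sources used here, so these signals were not turned into amounts.

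Arrays of slides 1 and 3 differed from those of slides 2 and 4 within every group. Of the variance within groups 37.0% followed this split, against 9.75% and 7.61% for the other 2 ways of pairing the slides. In the test of array brightness, this share was 7.27 times that of the next pairing among the brightest genes (3.38 among the dimmest). That argues against noise of dim spots as the whole cause. It cannot exclude array brightness, which could also act on bright genes. The tables argue against the signal distribution of the arrays, since the ratio over all genes was 3.38 after quantile normalization. They also argue against a straight-line trend on the base content of the probes, since the ratio was 3.60 after that was removed from each array. Tissue digestion cannot be told apart from other sources, because the ratio in monocytes alone was 1.496 and lay at the limit set for the test, and because the labels carry the cardiac digestion text on the monocyte samples too and give none for blood. The slides may differ in day, handling or animals, none of which the labels give, and in all 4 groups both arrays of slides 1 and 3 were also dimmer than both of slides 2 and 4 by the 75th percentile and by the share of spots well above background, for a reason not tested. No biological explanation was tested, since the design gives none for the slides.

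As a description only, since the split was found in these data and sets 2 slides against 2, limma called 10318 of 21897 genes between its sides, 4141 higher and 6177 lower in slides 1 and 3. Higher were 23 of 28 lysosome and 20 of 27 oxidative phosphorylation genes, and lower were 8 of 13 T and natural killer cell and 4 of 9 erythroid and platelet genes, with 0 in the other direction in each of these lists. None of the 28 lists passed camera with an estimated correlation.

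Cardiomyocyte transcripts were higher in heart macrophages than in blood monocytes, although the gates required CD45, MerTK and CD64. On the log2 scale relative to the 75th percentile, Myl3 averaged 2.87 in MHCII-high macrophages and -1.29 in monocytes, and Mb averaged 2.08 in MHCII-high macrophages and was not well above background on any monocyte array. None of the 16 listed genes is on another list, and how many of them macrophages express themselves was not measured here. The tables argue against dimmer monocyte arrays, since quantile normalization kept 0.9897 of the list median (2.80 to 2.77, with 2.29 under normexp and 2.50 with dim genes at their bound). RNA carried over from other heart cells may contribute: over the macrophage arrays, with group and slide means removed, the 15 measured members had a median pairwise correlation of 0.2499, at percentile 99.92 of 10000 matched random lists.

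That measure is not specific to carry-over, since the resident macrophage list reached 0.4998, above all 1000 matched random lists, while the endothelial list lay at percentile 38.6 and the fibroblast list at 72.3. Uptake of cardiomyocyte material by macrophages and RNA set free during digestion would both give such values, and the data hold no test between them. Expression by macrophages themselves stays open too.

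Columns of the deposited value table matched the arrays of other samples, 16 of 16, and 12 of them an array of another group. Scanner files under the wrong labels are argued against, since 14 of 15 gate checks, which leave out Fcgr1, passed under the scanner labels. The test of value table columns under the wrong labels gave 0 of 15 checks passed under the labels of the table, so mislabelled columns may explain the mismatch. No biological explanation was tested, since the same scans give both sets of values.

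For the counts of genes between groups, the arrays of each pair were split in all 35 ways, without regard to slides. For CCR2+ against MHCII-high macrophages only 1 split, the real one, gave as many as 273 genes (highest other 58), and for CCR2+ against MHCII-low macrophages only 1 gave as many as 607 (highest other 220). Against monocytes 1 split gave as many for CCR2+ (4744, highest other 4), MHCII-high (4686, highest other 2) and MHCII-low macrophages (4660, highest other 1). For the mean of the macrophage groups against monocytes, of 100 relabellings of all 16 arrays 1, the real one, gave as many as 5990 (highest other 1705). Of 100 relabellings within slides, which keep the pairing of arrays, also 1 did (highest other 1094). No random relabelling drawn thus reached the real count. Relabelling mixes the cell types and adds their difference to the spread within groups, so a lower count was likely beforehand. For MHCII-high against MHCII-low macrophages 2 of 35 splits gave as many as 15 genes, so over these splits chance cannot be excluded for that count. The other split was slides 1 and 3 against slides 2 and 4 with 99 genes, several times the real count, which points to a structure of the samples, and the count with the replicate as a block was 77. That split also gave the highest other count for both comparisons of CCR2+ with CCR2-negative macrophages and for CCR2+ macrophages with monocytes.

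Since replicate numbers were taken to pair the arrays, the real split of each pair of groups also has to be set against the 8 splits that part all 4 slide pairs, itself included. The highest other count among them was 1 for CCR2+ against MHCII-high and for MHCII-high against MHCII-low macrophages and 0 in limma for the other 4 pairs of groups. A set of 8 splits is too small for a share under 0.05.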

How the results depend on the processing

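The fits to slides 1 and 3 and to slides 2 and 4 alone were chosen after the data were seen, and all other alternatives before. No difference of a named gene reversed under the alternatives run for it. Where no cause is named below, the cause was not tested.

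With the replicate block, which takes out differences between slides, counts were higher: 549 for CCR2+ against MHCII-high, 1253 for CCR2+ against MHCII-low and 77 for MHCII-high against MHCII-low macrophages, 7394 for CCR2+ and 7050 for MHCII-low macrophages against monocytes. It kept 269 of the 273 calls, 604 of the 607 and 15 of the 15 between macrophage groups. Array weights gave 932, 1204 and 89 in these 3 comparisons, and a mean-variance trend with robust eBayes gave 27 for MHCII-high against MHCII-low macrophages.

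Scaling to the median gave 172, 377 and 4 between the macrophage groups. Fits to the compared groups only gave 330 for CCR2+ against MHCII-low and 0 for MHCII-high against MHCII-low macrophages (758 at an unadjusted p under 0.05 in limma), with fewer arrays to estimate the spread. Without a filter on dim probes the count was 8465 for CCR2+ macrophages and 9616 for the mean of the macrophage groups against monocytes. A 2-fold minimum left 2934, 2998 and 3025 for CCR2+, MHCII-high and MHCII-low macrophages against monocytes and 3049 for their mean. Quantile normalization, normexp, a filter of 8 arrays and the mean over probes kept all 7 counts within 1.5 times. With the mean over probes, calls in the opposite direction numbered 4, 2 and 3 for CCR2+, MHCII-high and MHCII-low macrophages against monocytes and 3 for their mean. The share of calls higher against monocytes changed side: for the mean it was 45.4%, with 29.4% under normexp, 50.9% under quantile normalization, 57.9% with a 2-fold minimum and 51.8% in slides 1 and 3 alone.

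Slides 2 and 4 alone gave 34, 305 and 2 between the macrophage groups, and slides 1 and 3 alone 2, 67 and 0 (943 unadjusted in limma), with fewer arrays. Against monocytes, slides 1 and 3 gave 1467, 1785 and 1858 for CCR2+, MHCII-high and MHCII-low macrophages and 2933 for the mean.

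The value table under its own labels gave 0 genes in all 7 comparisons in limma. At an unadjusted p under 0.05 it gave 315, 467 and 594 for CCR2+ against MHCII-high, CCR2+ against MHCII-low and MHCII-high against MHCII-low macrophages, 316, 419 and 202 for the pairs with monocytes and 246 for the mean. All of these lie below the share of 0.05 that chance alone would give.

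Leaving out 1 array at a time gave 153 to 217 for CCR2+ against MHCII-high, 406 to 652 for CCR2+ against MHCII-low, 0 to 18 for MHCII-high against MHCII-low macrophages, 3803 to 4412, 3861 to 4463 and 3954 to 4612 for CCR2+, MHCII-high and MHCII-low macrophages against monocytes, and 4966 to 6118 for their mean. The first count was 160 without CCR2+ replicate 1, 153 without CCR2+ replicate 2 and 166 without MHCII-high replicate 3. The third was 2, 8 and 4 without MHCII-high replicates 1, 3 and 4, and 0 without MHCII-low replicate 2 (1011 unadjusted in limma) or 3 (662 unadjusted).

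Of 196 list tests 109 passed, 49 passed with an estimated correlation, 103 with fry and 106 with the replicate block. The block ended the calls of the efferocytosis list (adjusted p = 0.0123 to 0.104) and of the inflammasome list (0.0468 to 0.104) between MHCII-high and MHCII-low macrophages, with medians of -0.21 and 0.02, and of the erythroid list in the 4 comparisons with monocytes (median -0.48 and adjusted p = 0.0291 to 0.0901 for the mean of the macrophage groups).

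Of 433 values of named genes 408 were past the threshold, and leaving out some array ended 58 of these calls. Between CCR2+ and MHCII-high macrophages those were Ly6c1, H2-DMb2, Vsig4, Chil3, Il1rn, Ccl17, Ctsf, Adam8, Nr4a2, Spic and Cd209a. Between MHCII-high and MHCII-low macrophages they were all 11 named genes past the threshold. Between CCR2+ and MHCII-low macrophages and against monocytes, no gene named above was among them. Median scaling ended 32 calls, normexp 23, quantile normalization 8 and the replicate block 1, Chil3 between CCR2+ and MHCII-high macrophages (adjusted p = 0.0461 to 0.0589, and from 0.0156 with normexp to 0.172 with an array left out over its alternatives, with a log2 difference of 2.21 and 2.36 in those). The planned use of the value table for single genes was not run, since its columns carry other labels.

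Signal over background limits what can be seen of dim genes: 7909 probes were never well above background on any array, and 52.8% to 60.1% of spots were well above it on monocyte arrays against 58.1% to 69.3% on macrophage arrays.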

Other observations

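Many oxidative phosphorylation genes were lower in heart macrophages than in blood monocytes, while glycolysis genes went both ways. Of 27 oxidative phosphorylation genes 17 were lower in the mean of the macrophage groups than in monocytes, 0 higher and 10 not past the threshold, and 22 were lower when adjusted over the list alone. Uqcrfs1, the iron-sulphur subunit of complex III (-1.81 ± 0.20, adjusted p = 4.29e-06), and Ndufb5 of complex I (-1.22 ± 0.15, adjusted p = 2.07e-05) were examples. The list had a median of -0.59 (camera adjusted p = 6.45e-07, but adjusted p = 0.371 with an estimated correlation). Within groups this list was also higher on slides 1 and 3, the dimmer arrays (20 of 27 genes higher, 0 lower, median 0.41). Monocyte arrays were dim too, with a 75th percentile of 819 to 996 against 941 to 1670 on macrophage arrays. Whether array brightness contributes to the difference from monocytes was not tested. Glycolysis genes had 3 higher, 8 lower and 8 not past the threshold, the same as when adjusted over the list alone, with Pfkm higher (1.61 ± 0.30, adjusted p = 0.000685) and hexokinase 2, Hk2, lower (-1.41 ± 0.32, adjusted p = 0.00364). That list did not pass camera (median -0.29, adjusted p = 0.24), and its direction in camera turned with normexp. Lysosome genes were higher for 11 of 28, lower for 5 and not past the threshold for 12, with 13 higher and 5 lower when adjusted over the list alone. The tetraspanin Cd63 was at least 68.4-fold higher (adjusted p = 2.54e-12) and the protease Ctsl was higher by 2.54 ± 0.34 (adjusted p = 3.79e-05). The lysosome list had a median of 0.20 (camera adjusted p = 0.00229, but adjusted p = 0.594 with an estimated correlation).

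Antiviral and class I genes were measured too. Interferon-stimulated genes were higher in CCR2+ than in MHCII-high macrophages as a list, with a median of 0.33, from 0.07 to 0.74 by slide (camera adjusted p = 7.39e-08, but adjusted p = 0.214 with an estimated correlation). In limma 0 of the 24 passed over all genes, 4 were higher when adjusted over the list alone, and 2 passed with the replicate as a block. Against monocytes 4 were higher in the mean of the macrophage groups, 3 lower and 17 not past the threshold (4 higher and 5 lower when adjusted over the list alone), with the antiviral synthase gene Oas3 lower (-1.94 ± 0.23, adjusted p = 1.23e-05) and the tethering protein gene Bst2 higher (0.90 ± 0.21, adjusted p = 0.0046). The interferon list did not pass there (median -0.35, camera adjusted p = 0.271). MHC class I presentation genes had 1 higher, 4 lower and 9 not past the threshold, with 1 higher and 7 lower when adjusted over the list alone. The proteasome activator Psme1 was lower (-0.91 ± 0.19, adjusted p = 0.00179), and the class I list did not pass camera (median -0.43, adjusted p = 0.106).

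Markers of lymphocytes and neutrophils were measured as well. T and NK cell genes had 0 higher, 1 lower and 12 not past the threshold against monocytes (median -0.41, camera adjusted p = 0.549), and 0 in limma when adjusted over the list alone. B cell genes had 0 higher, 1 lower and 7 not past the threshold, also 1 when adjusted over the list alone (median -0.20, camera adjusted p = 0.549). Neutrophil genes had 2 higher, 3 lower and 6 not past the threshold, with 2 higher and 4 lower when adjusted over the list alone (median -0.42, camera adjusted p = 0.271). The neutrophil collagenase Mmp8, well above background on 1 of 4 MHCII-low arrays and 2 of 4 in each other macrophage group, was lower by -5.90 ± 0.73 (adjusted p = 1.68e-05) and Cd177 by -3.21 ± 0.34 (adjusted p = 2.92e-06).

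The test that follows was chosen after the results of the single comparisons had been seen. The hypothesis is that CCR2+ macrophages lie nearer to the monocyte profile than MHCII-high macrophages do. Genes were taken from a fit to monocytes and MHCII-low macrophages only (3691 genes), so that no array served on both sides. The covariance across these genes of the monocyte minus MHCII-low difference with the CCR2+ minus MHCII-high difference was 0.881, the highest of the 35 splits of the 8 CCR2+ and MHCII-high arrays, with 0.532 as the highest other. That other split is among the 8 that part all 4 slide pairs, and 8 splits are too few for a share under 0.05. The differences had the same sign for 67.9% of the genes, and their correlation across genes was 0.548. This fits the hypothesis, and CCR2+ macrophages may thus be closer to monocytes in origin or in state, or the sort may have let some monocytes into the CCR2+ gate, which the test does not part.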
